A study of Mus musculus with 4 samples.

How the data were processed

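RNA from the left hippocampus of male mice aged 12 months was measured on 4 Affymetrix oligonucleotide arrays. Per the labels, 2 arrays came from nontransgenic controls (C57B6/SJL) and 2 from Tg2576 mice, called APPSw, and each array is described as holding the RNA of a mouse. The labels do not state that the mice were different animals or littermates, so p-values measure the spread between these samples, which may be partly technical. The number of arrays, 2 per group, limits the precision of every comparison.

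The deposited values are linear signal intensities, 1 per probe set and array, which the authors made with MAS 5.0 and scaled to a target of 2500, per the labels. A probe set is the group of short probes that stands for a transcript. The mean signal after trimming 2% of the values at each end was 2501 on every array, and 0 values were at or below 0. The background settings, the labelling kit, the scanner and the RNA quality are not given in the sources used here. MAS 5.0's present and absent calls and the probe-level images were not used here.

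The table holds 12488 probe sets, of which 66 are manufacturer's controls and were left out of the comparisons. Of the other 12422, the platform annotation pairs 10833 with 1 gene symbol (8251 genes), 396 with several and 1193 with none. The gene identifiers of 10817 were found in the current RefSeq gene table (GRCm38.p6), and 0 symbols needed an update. No gene was named from a probe set paired with several. Probe sets whose mean log2 signal over the arrays lay under the 40th percentile, a geometric mean signal of 565, were left out, which kept 7453 probe sets and 5670 genes. No further normalization was applied.

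Log2 signals of APPSw and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 7453 probe sets and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom and 3.70 prior degrees of freedom. A difference in log2 is APPSw minus control, and its SE is limma's moderated one. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

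Lists of genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 22 lists with 5 or more kept genes, with camera at a correlation estimated from each list and limma's fry beside it. Each gene was represented by its kept probe set with the highest mean signal. Of 24 lists, 12 hold markers of cell types or neighbouring regions (choroid plexus epithelium, meninges and fibroblasts, ependymal cells, endothelium and mural cells, erythrocytes, astrocytes, microglia, oligodendrocytes, hippocampal principal neurons, interneurons, striatum and thalamus, and neocortex). The other 12 hold pathways (amyloid precursor protein processing and binding, the insulin-like growth factor axis, apoptosis and survival, antioxidant genes and NRF2 targets, heat shock and the unfolded protein response, activity-induced genes, synaptic transmission, oxidative phosphorylation, cholesterol synthesis, complement with MHC class I and cytokine signalling, thyroid hormone and retinoid transport and response, and ribosomal proteins).

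The groups, the tests of the groups and of the lists, the lists themselves, the alternatives and the rule for naming genes were fixed before the data were examined. The tests of explanations in the closing section were not among these. The rule names App, Prnp, Ttr, Igf2, Igfbp2, Gfap and Apoe in any case. It adds the 10 genes with the smallest p in each direction among probe sets with both APPSw arrays on the same side of both controls. It also adds up to 4 members of each list past the threshold and up to 2 of each other tested list, those with the largest moderated statistic. Ttr, Igf2 and Igfbp2 were chosen because published work on this mouse line reports them.

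The fit was tested on simulated data over 20 runs of 7453 probe sets. Means were those of the real probe sets, and variances were drawn from limma's fitted prior. Errors were normal and independent between probe sets, so the rates hold only under the fit's own assumptions. The fit recovered 86.9% of probe sets changed 4-fold and 10.6% of those changed 2-fold at the adjusted threshold. It called 0.15 unchanged probe sets per run. The alternatives were quantile normalization, no filter, a filter at the 60th percentile, a floor of 250, a pseudocount of 250, the replicate number as a block, an intensity trend in the prior variance, the mean of a gene's probe sets, an estimated inter-gene correlation, the choroid plexus list without Ttr, Igf2 and Igfbp2, and each array left out in turn. With an array left out, the lone array of its group is assumed to vary like the other group.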

Results

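Gene expression was measured in the left hippocampus of 12-month-old male mice, with 2 arrays from nontransgenic controls (C57B6/SJL) and 2 from Tg2576 mice (APPSw). The Tg2576 line carries a transgene for amyloid precursor protein with the Swedish mutation and is a widely used model of cerebral amyloid deposition. The comparison asks which hippocampal transcripts differ between transgenic and nontransgenic animals. Median signals were 926 and 988 on control arrays 1 and 2, and 1033 and 1013 on APPSw arrays 1 and 2. A probe set differed by a median of 1.14-fold between the control arrays, by 1.18-fold between the APPSw arrays, and by 1.176-fold to 1.198-fold between a control and an APPSw array.

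App, the mouse gene for amyloid precursor protein, had a mean signal of 89889 ± 7054 (SD, n = 2) in controls and 89910 ± 9229 (SD, n = 2) in APPSw mice. Its log2 difference of -0.0013 (SE 0.18, adjusted p = 0.999) had no stable sign, and was 0.07 after quantile normalization, 0.08 without control 2 and 0.10 without APPSw 2. Prnp, the prion protein gene, had a log2 difference of -0.08 (SE 0.18, adjusted p = 0.914), which was 0.02 without APPSw 1. The transgene places a human APP coding sequence in a hamster prion protein gene vector. The position of the mouse probes against those sequences is not given in the sources used here, so these values check neither the transgene nor the labels.

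Apoe, the main lipid carrier of the brain, had a log2 difference of -0.14 (SE 0.17, adjusted p = 0.823). Gfap, an intermediate filament of reactive astrocytes, had signals of 2684 and 2569 in controls and 2025 and 1126 in APPSw mice by the dimmer of its probe sets, a log2 difference of -0.80 (SE 0.30, adjusted p = 0.610). The brighter Gfap probe set gave -0.24 (SE 0.31), and 0.19 without APPSw 2. Neither gene passed the test.

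The 10 genes with the smallest p in each direction differed by factors of 1.85 to 5.09, but no probe set passed the adjusted threshold. They were chosen for having both APPSw arrays on the same side of both controls. The largest factor came from 1 of several Csnk1d probe sets. Both controls lay under the filter's signal of 565 for Foxk1 and Pspn, and both APPSw arrays for Csnk1d, Fcgbp and Hcrt. With limma, 0 of 7453 probe sets were called higher and 0 lower, and the lowest adjusted p was 0.599. At an unadjusted p under 0.05 there were 600 probe sets, 352 higher and 248 lower, where chance alone gives 373. Both APPSw arrays lay on the same side of both controls for 41.2% of probe sets, against 33.3% by chance. For 64 higher and 27 lower ones, each APPSw array was at least 1.5-fold from each control array.

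Among the 10 higher genes, Kcna1, a voltage-gated potassium channel of axons, had signals of 2673 and 3290 in controls and 9087 and 6720 in APPSw mice, a log2 difference of 1.40 (SE 0.23). The transcription factors Foxk1 and Sox11 differed by 1.75 (SE 0.26) and 1.196 (SE 0.22). Med1, a subunit of the Mediator complex, differed by 1.90 (SE 0.37), and Pspn, a neurotrophic factor of the GDNF family, by 2.03 (SE 0.40). Dsg2, a desmosomal cadherin, differed by 1.12 (SE 0.17), Capn6, of the calpain family, by 1.07 (SE 0.17), and Utrn, the dystrophin relative utrophin, by 0.98 (SE 0.19). Dimmer probe sets left out by the filter differed by -0.97 and 0.28 for Capn6, -0.25 for Utrn, 0.09 for Dsg2 and 0.69 for Sox11. Xrn1, an RNA exonuclease, differed by 0.96 (SE 0.19). Sf3b1, a splicing factor, differed by 0.99 (SE 0.18), while its other kept probe set differed by -0.04. The adjusted p was 0.599 for each of them.

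Among the 10 lower genes, Hcrt, which encodes the hypocretin neuropeptides, had signals of 797 and 1323 in controls and 431 and 303 in APPSw mice, a log2 difference of -1.51 (SE 0.31). Eef1b2, a translation elongation factor, differed by -1.61 (SE 0.29), Cherp by -1.29 (SE 0.26), and Adh7, an alcohol dehydrogenase, by -0.94 (SE 0.17). For several genes other probe sets gave another value. Csnk1d, casein kinase 1 delta, differed by -2.35 (SE 0.30) by 1 probe set and by -0.18, -0.09 and 0.24 by its others. B3gnt2, a glycosyltransferase, differed by -1.91 (SE 0.33), and its other probe set by 0.29. Fcgbp differed by -1.45 (SE 0.27) and 0.09, the splicing factor Srsf1 by -0.89 (SE 0.17) and -0.08, and Ankrd40 by -1.15 (SE 0.20) and -0.25. Actb, cytoskeletal beta-actin, differed by -1.23 (SE 0.25) and -0.66, while the manufacturer's 3' beta-actin control probe set differed by 0.35. The adjusted p was again 0.599 for each of the 10.

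Of 22 lists tested, 7 passed camera's threshold, 4 higher and 3 lower in APPSw mice. With an estimated correlation 0 lists passed (adjusted p = 0.760 for each of the 7). Of the 7, 4 still passed without control 2, 3 without APPSw 2 and 4 with no filter. With an estimated correlation, camera takes its degrees of freedom from the fit, which had 2, so hardly any list could pass. The estimated correlations were 0.93 for choroid plexus, 0.55 for oligodendrocytes, 0.29 for meninges and fibroblasts, 0.28 for synaptic transmission and 0.07 for principal neurons. These exceed the preset 0.01, so for these lists correlated genes and the few degrees of freedom cannot be told apart. For cholesterol synthesis and neocortex the estimated correlations were -0.05 and -0.17. Their unadjusted camera p still rose from 0.0017 to 0.077 and from 0.0041 to 0.0996, so these lost calls do not show correlated genes. By fry, 0 lists passed in a single direction, and 2 passed for change in either direction. Over all probe sets 0 members of the lists passed limma's test, and adjusted over the list alone 2 genes passed, both in the neocortex list.

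**Figure D1:**
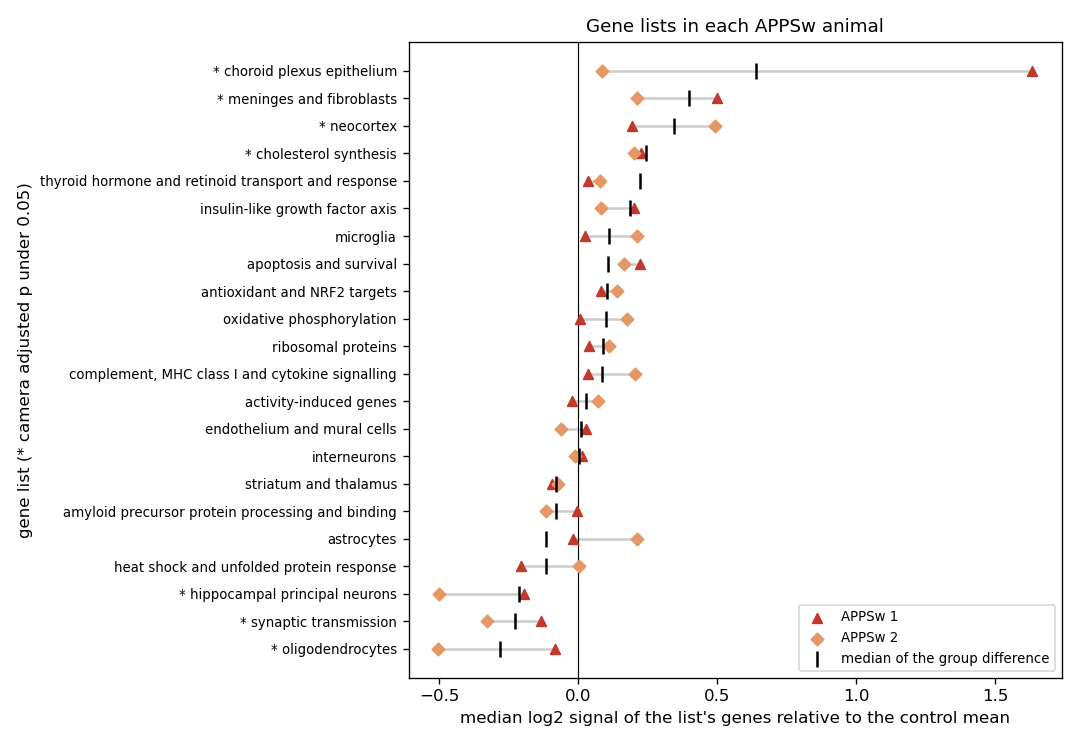
Median log2 signal of each list's genes relative to the control mean, in APPSw 1 (triangles) and APPSw 2 (diamonds), with the median of the group difference as a bar and an asterisk for camera's adjusted p under 0.05. The choroid plexus list lay at 1.63 in APPSw 1 and 0.09 in APPSw 2.

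Markers of the choroid plexus epithelium, which makes cerebrospinal fluid beside the hippocampus, were higher as a list in APPSw mice (camera adjusted p = 0.0063, and adjusted p = 0.760 with an estimated correlation), and the difference came from APPSw 1. Ttr, the thyroxine carrier transthyretin, had signals of 8908 and 1896 in controls, 83384 in APPSw 1 and 3236 in APPSw 2. Igf2, insulin-like growth factor 2, had 7895 and 7724 in controls, 30368 in APPSw 1 and 9464 in APPSw 2. Igfbp2, an insulin-like growth factor binding protein, had 3567 and 2798 in controls, 9724 in APPSw 1 and 2490 in APPSw 2. The log2 differences were 2.00 (SE 1.55, adjusted p = 0.722) for Ttr, 1.12 (SE 0.52, adjusted p = 0.612) for Igf2 and 0.64 (SE 0.61, adjusted p = 0.773) for Igfbp2. Without APPSw 1, Ttr was -0.34, Igfbp2 was -0.34 and Igf2 was 0.28.

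The choroid plexus list rose by a median of 1.56-fold over its 14 measured genes, of which 13 lay above 0 and 1 below (camera adjusted p = 0.0063, and adjusted p = 0.760 with an estimated correlation). By limma 0 of the 14 passed singly, over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The folate receptor gene Folr1 had a log2 difference of 1.5025 (SE 0.82), Lbp, a lipopolysaccharide-binding protein, 1.12 (SE 0.61), and Cox8b, a cytochrome c oxidase subunit, 0.73 (SE 0.28). Without APPSw 1 these were 0.35, 0.19 and 0.43. All 14 genes were brightest in APPSw 1, where the list's median was 3.10-fold above the control mean, against 1.06-fold in APPSw 2. Without APPSw 1 the median log2 difference was 0.09 (camera adjusted p = 0.765, direction down), and without APPSw 2 it was 1.63.

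Genes of meninges and fibroblasts rose by a median of 1.32-fold, with 12 of 13 above 0 (camera adjusted p = 0.0063, and adjusted p = 0.760 with an estimated correlation). The collagen gene Col1a1 differed by 0.57 (SE 0.19), Mgp, a matrix calcification inhibitor, by 0.68 (SE 0.23), the proteoglycan gene Dcn by 0.65 (SE 0.32) and the GABA transporter gene Slc6a13 by 0.56 (SE 0.26). Dcn had signals of 3716 and 6907 in controls and 7406 and 8587 in APPSw mice. Slc6a13 lay 0.89 above the control mean in APPSw 1 and 0.24 in APPSw 2. By limma 0 of the 13 passed singly, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. The list's median was 0.50 in APPSw 1, the array with the higher choroid plexus markers, and 0.21 in APPSw 2. For control 1 minus control 2 it was -0.21. The call ended without APPSw 1 (median 0.21, adjusted p = 0.329) and with no filter (median 0.18, adjusted p = 0.215), and without control 1 the median was 0.24.

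**Figure D2:**
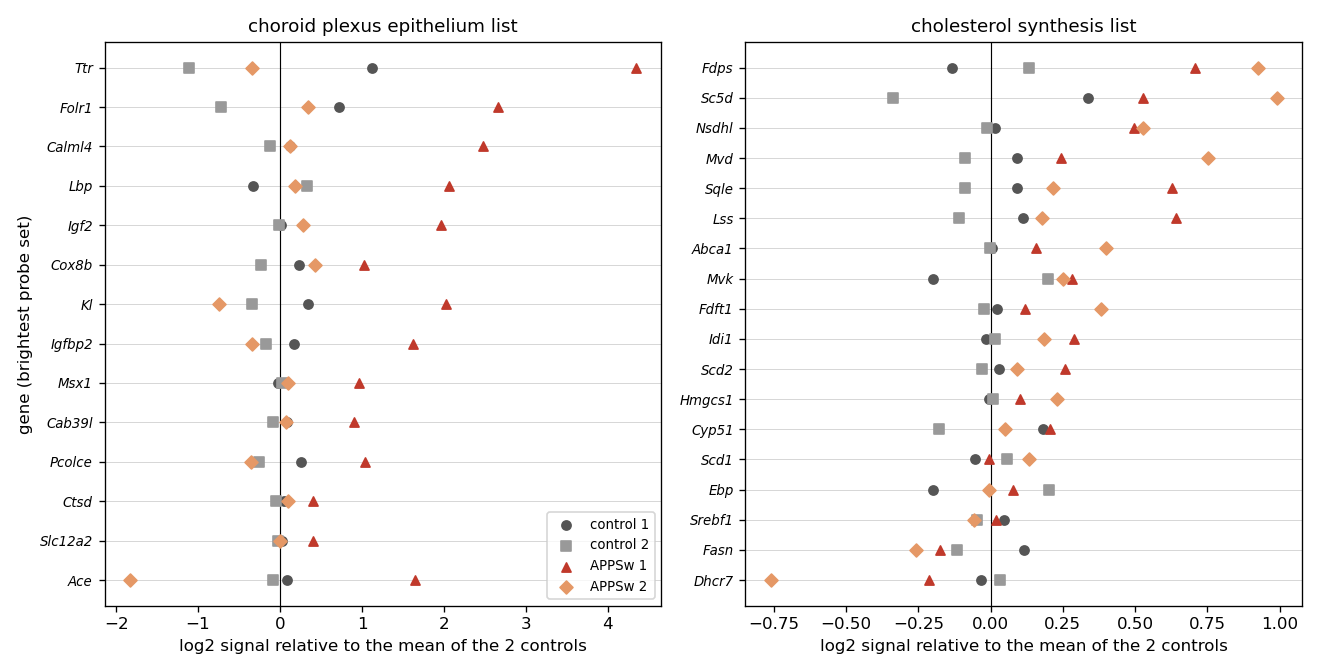
Log2 signal of each gene of the choroid plexus list (left) and the cholesterol synthesis list (right) relative to the mean of the 2 controls, with 1 point per array. All 14 choroid plexus genes were brightest in APPSw 1, and of the 18 cholesterol genes 15 lay above the control mean in APPSw 1 and 14 in APPSw 2.

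Genes of cholesterol synthesis rose by a median of 1.18-fold, with 15 of 18 above 0 and 3 below (camera adjusted p = 0.0090, and adjusted p = 0.760 with an estimated correlation). Fdps, which makes farnesyl diphosphate, had signals of 6259 and 7519 in controls and 11189 and 13027 in APPSw mice, a log2 difference of 0.82 (SE 0.19), and 0.39 by its other kept probe set. The sterol enzymes Nsdhl and Sc5d differed by 0.51 (SE 0.17) and 0.76 (SE 0.29), and Mvd, of the mevalonate pathway, by 0.50 (SE 0.23). Other kept probe sets differed by 0.61 and 0.16 for Nsdhl and by 1.10 for Sc5d. By limma 0 of the 18 passed singly, also adjusted over the list alone, and 3 had an unadjusted p under 0.05. The median lay 0.22 above the control mean in APPSw 1 and 0.20 in APPSw 2, while the controls differed by 0.04. The call ended without control 2 (median 0.24, adjusted p = 0.078) and with no filter (median 0.20, adjusted p = 0.139).

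Neuronal lists moved both ways. Markers of hippocampal principal neurons fell, with a median log2 difference of -0.21 and 11 of 14 below 0 (camera adjusted p = 0.0090, and adjusted p = 0.760 with an estimated correlation). Bok, a BCL2 relative, had signals of 9912 and 6633 in controls and 4542 and 4902 in APPSw mice, a log2 difference of -0.78 (SE 0.24). The proteoglycan gene Spock1 differed by -0.71 (SE 0.19), Lct, the lactase gene, by -0.53 (SE 0.18) and Tdo2, which degrades tryptophan, by -0.58 (SE 0.26). By limma 0 of the 14 passed singly, also adjusted over the list alone, and 3 had an unadjusted p under 0.05. The call ended without control 1 (median -0.23, adjusted p = 0.088) and without APPSw 2 (median -0.20, adjusted p = 0.107), and without APPSw 1 the median was -0.50. Without control 2 it was -0.34. The list's median for control 1 minus control 2 was 0.22, about as large in size as the group difference.

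Genes of synaptic transmission fell too, with a median of -0.23 and 16 of 25 below 0 (camera adjusted p = 0.013, and adjusted p = 0.760 with an estimated correlation). Syp, the synaptic vesicle protein synaptophysin, had signals of 10209 and 10195 in controls and 6928 and 7347 in APPSw mice, a log2 difference of -0.52 (SE 0.17). Rab3a, a vesicle GTPase, differed by -0.999 (SE 0.28), Vamp2, a vesicle fusion protein, by -0.50 (SE 0.18), and Nrgn, the postsynaptic calmodulin-binding protein neurogranin, by -0.71 (SE 0.24). By limma 0 of the 25 passed singly, also adjusted over the list alone, and 7 had an unadjusted p under 0.05, 6 of them lower. The list's median for control 1 minus control 2 was -0.20, close in size to the group difference. The call ended without control 2 (median -0.05, adjusted p = 0.733), without APPSw 2 (median -0.13, adjusted p = 0.107) and with the stricter filter (adjusted p = 0.092).

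Markers of neocortex rose, with a median of 0.34 and 5 of 5 above 0 (camera adjusted p = 0.013, and adjusted p = 0.760 with an estimated correlation). Fezf2, a transcription factor of deep-layer projection neurons, had signals of 4410 and 3797 in controls and 7471 and 7451 in APPSw mice, a log2 difference of 0.87 (SE 0.18). Mef2c, a neuronal transcription factor, differed by 0.93 (SE 0.22) by its brightest probe set and by 0.51, 0.65 and -0.06 by its others. These 2 genes passed limma's test adjusted over the list alone, with a lowest p of 0.015 by that adjustment, and not over all probe sets. The transcription factors Nr4a2 and Tbr1 had differences of 0.34 (SE 0.32) and 0.22 (SE 0.23), and the remaining gene, Cux1, 0.02 (SE 0.20), which is named here after its value was seen. The call ended without control 1 (median 0.14), where Nr4a2 was -0.09, and without APPSw 2 (median 0.19), where Tbr1 was -0.05. It also ended with no filter (camera adjusted p = 0.094), where the median stayed at 0.34 over 7 genes. Without control 2 the median was 0.76, and for control 1 minus control 2 the list's median was -0.16.

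Oligodendrocyte genes fell, with a median of -0.28 and 9 of 9 below 0 (camera adjusted p = 0.0090, and adjusted p = 0.760 with an estimated correlation). Ugt8a, which makes the myelin lipid galactosylceramide, differed by -0.63 (SE 0.31), with signals of 608 and 1091 in controls and 569 and 490 in APPSw mice. Mal, a myelin proteolipid, differed by -0.29 (SE 0.17), and Cldn11, a tight junction protein of myelin, by -0.28 (SE 0.19). Mag, myelin-associated glycoprotein, had signals of 5088 and 6153 in controls and 5278 and 3163 in APPSw mice, a difference of -0.45 (SE 0.29), and 0.25 by its other probe set. By limma 0 of the 9 passed singly, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. The list's median was -0.08 in APPSw 1 and -0.50 in APPSw 2. For control 1 minus control 2 it was -0.27, about as large as the group difference. The call ended without APPSw 2 (median -0.08, adjusted p = 0.526) and without control 2 (median -0.20, adjusted p = 0.174), and the median was -0.44 without control 1 and -0.50 without APPSw 1.

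The remaining 15 lists tested did not pass camera's threshold, and their medians were at most 0.22 in size. In the heat shock and unfolded protein list (median -0.12 over 24 genes, adjusted p = 0.063), the chaperone genes Hsph1 and Hspa1b had differences of -0.43 and -0.64. In oxidative phosphorylation (0.10 over 47, adjusted p = 0.087), Atp5g2 had 0.47 and Cox7b 0.53. In apoptosis and survival (0.11 over 20, 0.08 to 0.22 with an array left out, adjusted p = 0.186), the death promoter Bad had 0.52 by both its probe sets, and Tnfrsf1a, a TNF receptor, had 0.70 and -0.55 by different probe sets. Among antioxidant genes and NRF2 targets (0.10 over 26, adjusted p = 0.233), glutathione reductase, Gsr, had 0.72 and catalase, Cat, 0.35. Apoptosis and the antioxidant list were the 2 that fry called for change in either direction (adjusted p = 0.048 each). The heat shock list's median was -0.20 without APPSw 2 and 0.0028 without APPSw 1, so its fall came from APPSw 1. Without APPSw 2 the heat shock list passed camera's threshold. Oxidative phosphorylation passed camera's threshold after quantile normalization (0.12, adjusted p = 0.024) and with the stricter filter (0.09, adjusted p = 0.022). It also passed without control 1 and without APPSw 1. Its median was 0.18 without control 1, 0.18 without APPSw 1, 0.0072 without APPSw 2 and 0.055 without control 2.

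The immune, microglial, astrocyte and endothelial lists did not pass. In complement, MHC class I and cytokine signalling (0.09 over 14, 0.02 to 0.27 with an array left out, adjusted p = 0.335), the antigen presentation genes Cd74 and Psmb8 had differences of 0.79 and 0.93. Psmb8 had signals of 700.5 and 791.8 in controls, 1052.0 in APPSw 1 and 1922.7 in APPSw 2. In microglia (0.11 over 14, 0.02 to 0.22 with an array left out, adjusted p = 0.601), where camera's direction was down without control 2 and without APPSw 2, C1qc had -0.62, and Csf1r had -0.48 by 1 probe set and 0.64 by another. In astrocytes (median -0.12 over 15 with a mean of -0.00016, adjusted p = 0.806), the glutamate transporter Slc1a2 had -0.41 and glutamine synthetase, Glul, 0.53. Against the control mean Glul was 0.83 in APPSw 1 and 0.24 in APPSw 2, and its other kept probe set had a difference of 0.33. The astrocyte list's median was 0.21 without APPSw 1. Endothelium and mural cells had a median of 0.01 over 11 genes and a mean of -0.08, with camera's direction down (adjusted p = 0.484) and a median of -0.07 after quantile normalization. There Pdgfrb, a pericyte receptor, had -0.72 and the glucose transporter Slc2a1 had -0.49.

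In the insulin-like growth factor axis (0.19 over 16, 0.08 to 0.28 with an array left out, adjusted p = 0.338, direction down without APPSw 1), which holds Igf2 and Igfbp2, the insulin receptor substrate Irs2 had -1.19 (SE 0.74), and 0.01 without APPSw 2. In thyroid hormone and retinoid transport and response (0.22 over 11, adjusted p = 0.680), which holds Ttr and Nrgn, the retinol carrier Rbp4 had 0.83. That median was 0.01 with the stricter filter or the mean of a gene's probe sets, 0.05 with no filter and 0.03 to 0.12 with an array left out, with camera's direction down in the first 2 cases and without APPSw 1. The amyloid list (median -0.08 over 20, -0.11 to -0.0045 with an array left out, with a mean of 0.05, camera's direction down except without APPSw 2, adjusted p = 0.581) also holds Ttr, and there Apbb2 had 0.52 and Ide, an insulin- and amyloid-degrading protease, -0.46 by 1 probe set and 0.37 by another. Activity-induced genes (median 0.03 over 23 with a mean of -0.03, adjusted p = 0.581) had a median of -0.02 after quantile normalization, and Dusp6 had -0.63 and the immediate early gene Egr1 -0.81. Interneuron markers (median 0.0035 over 16 with a mean of -0.02, adjusted p = 0.601) had a median of -0.02 after quantile normalization, and Dlx2 had -0.55 and the neuropeptide gene Cort -0.65. In striatum and thalamus (-0.08 over 10, -0.15 to -0.04 with an array left out, adjusted p = 0.531), Foxp1 had 0.23 and proenkephalin, Penk, -0.22 by 1 probe set and 0.66 by another. Among ribosomal proteins (0.09 over 22, 0.02 to 0.11 with an array left out, adjusted p = 0.484), where camera's direction was down without control 2 and without APPSw 2, Rps13 had -1.204 and Rpl13a 0.58.

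The ependymal and erythrocyte lists kept fewer than 5 genes and were tested only with no filter, where neither passed (adjusted p = 0.691 and adjusted p = 0.313), and their genes are named after their values were seen. The ependymal median was 0.01 over 4 genes, with Foxj1 at -0.02, Rsph1 at -0.22, Mia at 0.19 and Pltp at 0.03. It was 0.28 in APPSw 1, the array with the higher choroid plexus markers, and -0.30 in APPSw 2. The haemoglobin genes Hba-a1 and Hbb-b2 of the erythrocyte list differed by 0.62 and 0.38.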

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

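The tests of choroid plexus tissue in 1 animal and of a like effect in both APPSw animals were chosen after the result was seen. So were those of cholesterol synthesis in 1 APPSw array alone and of the other splits of the arrays. The manufacturer's control probe sets were outside the comparisons of the report, and 6 of the 30 bright ones lay at least 1.2-fold higher in APPSw arrays, with both above both controls. In all, 9 of the 30 had both APPSw arrays above both controls, where chance gives 16.7%, against 1654 of the 7453 probe sets tested in the report, and 5 of the 9 are beta-actin probe sets, which are not independent. The log2 differences were 0.61 for the 3' probe set of 18S ribosomal RNA, 0.35, 0.34 and 0.46 for the 3', 5' and middle probe sets of beta-actin, 0.75 for the opposite strand of the middle of beta-actin, and 0.82 for the opposite strand of the 3' part of the spiked transcript CreX. The beta-actin controls ran opposite to the Actb probe sets, which differed by -1.23 and -0.66, and this was not explained by any test here.

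The choroid plexus list was 1.80 log2 higher in APPSw 1 than in APPSw 2 after quantile normalization and 1.78 as deposited, which argues against the scaling of the arrays. An effect of like size in both transgenic animals is argued against too, since the median in APPSw 2 was 5.27% of that in APPSw 1 and, at 0.09, lay under the list's median difference between the controls of 0.21. Choroid plexus tissue in the dissection of APPSw 1 stays open and is not supported by a separate test, since the median of 1.03 in APPSw 1 and 0.10 in APPSw 2 over the 11 genes other than Ttr, Igf2 and Igfbp2 restates the pattern. In APPSw 1, Ttr, Igf2 and Ctsd had signals of 83384, 30368 and 28921, which lay 4.34, 1.96 and 0.40 above their control means, and 13 of the 14 genes were above the filter's signal in both controls and 3 belong to other lists too. A response of the hippocampus or choroid plexus in this animal alone would give the same values, so it cannot be told apart from such tissue here.

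The cholesterol synthesis list lost its call with an estimated correlation (adjusted p = 0.760), without control 2 (adjusted p = 0.078) and with no filter (adjusted p = 0.139), and its higher median was weighed against 3 explanations. A single APPSw array as its source is argued against by medians of 0.22 in APPSw 1 and 0.20 in APPSw 2. Between the controls the list's median was 0.04. The labels do not state that the 2 APPSw arrays hold different animals, so a single animal is not excluded. Scaling is argued against by a median of 0.242 after quantile normalization and 0.243 as deposited. Brightness is argued against by 10000 random lists matched on signal, whose medians had a middle value of 0.013. Of these lists 0.07% had a median as high, but the list was taken up after camera's call, so this share is no separate test of its rise. A transgene effect may be among the open explanations, together with the animals' litters and a difference in dissection, since the neocortex list rose by a median of 0.34 and the principal neuron and oligodendrocyte lists differed by -0.21 and -0.28 in the same comparison.

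Probe sets with an unadjusted p under 0.01, of which there were 116, may partly reflect probe sets that do not follow their gene. They may also reflect chance, since no probe set passed the adjusted threshold. Of 37 with another kept probe set of the same gene, 67.6% went the same way (exact binomial 95% interval 50.2% to 82.0%). The median size of the 37 was 0.91. Signed in the direction of the first probe set, the median difference of the others was 0.08. The first were picked for a small p, which alone would leave the others nearer to no difference, so this gap does not tell the explanations apart. Name suffixes for shared or incomplete sequence were on 24.1% of the 116 and on 18.6% of the other probe sets tested (odds ratio 1.39, 95% interval 0.872 to 2.16, two-sided Fisher's exact p = 0.149). Neither the share going the same way nor the share with a suffix settles the matter, because both intervals hold values for and against it.

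The number of probe sets with an unadjusted p under 0.05 was 600 for the real groups, and the highest of the other splits of the arrays had 255. By limma's lowest adjusted p the real groups did not stand out. It was 0.599 for them, 0.401 for number 1 against number 2, and 0.978 for the remaining split. Of the 3 splits, 1 gave as many as 600, which is the real one, and 3 splits are too few for a share under 0.05.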

How the results depend on the processing

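None of the alternatives was chosen after the result was seen. In the alternatives that refitted the probe sets, 0 passed limma's threshold in either direction, with 402 to 816 at an unadjusted p under 0.05. The number of lists past camera's threshold was 8 after quantile normalization, 4 with no filter, 0 with an estimated correlation and 4 to 6 with an array left out. The choroid plexus median was 0.64 with an estimated correlation (adjusted p = 0.760), 0.53 without Ttr, Igf2 and Igfbp2 (adjusted p = 0.0090), and 0.086 to 1.63 with an array left out, and its call held in 10 of 12 alternatives besides the one without those genes. The replicate numbers are shared between the groups, but the labels do not say that they pair the animals, so they were not taken as pairs. Across probe sets, control 1 minus control 2 had a correlation of -0.02 with APPSw 1 minus APPSw 2. The replicate block left 7 lists past the threshold and the choroid plexus median at 0.64, and it changed no call. Of the named genes' values 874 kept their direction and 10 reversed, and of the values of the tested lists other than choroid plexus 208 kept direction and side of the threshold, 20 were lost, 5 were gained and 18 reversed. Reversed medians after quantile normalization were -0.066 for endothelium, -0.015 for interneurons and -0.024 for activity-induced genes, and App was 0.068. With no filter interneurons were at -0.032 and activity-induced genes at -0.047, and with the stricter filter at -0.032 and -0.13. With an array left out, medians ran from -0.062 to 0.029 for endothelium, -0.060 to 0.012 for interneurons, -0.080 to 0.070 for activity-induced genes, -0.12 to 0.21 for astrocytes and -0.20 to 0.0028 for heat shock. Likewise App ran from -0.11 to 0.10, Prnp from -0.19 to 0.021, Ttr from -0.34 to 4.34, Igfbp2 from -0.34 to 1.62, Gfap's brighter probe set from -0.67 to 0.19, Nr4a2 from -0.085 to 0.77, Tbr1 from -0.052 to 0.49 and Irs2 from -2.40 to 0.012. The stricter filter left too few endothelial genes to test. The cause of these differences was not tested. The background level is not given in the sources used here, so how far it limits dim signals was not tested.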

Other observations

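Some probe sets stood apart in single arrays, and the genes named here were chosen after their values were seen. APPSw 1 had 29 probe sets at least 2-fold above each other array, against 8 in APPSw 2, 3 in control 1 and 4 in control 2. The 29 include 22 named genes, of which 8 belong to the choroid plexus list. The pituitary hormone genes Gh and Prl were among them. Gh, growth hormone, had signals of 1820 and 2800 in controls, 12054 in APPSw 1 and 3330 in APPSw 2. Prl, prolactin, had 525 and 438 in controls, 1403 in APPSw 1 and 546 in APPSw 2. The homeobox gene Six2 had 2049 in APPSw 1 and 444 in APPSw 2, the cell cycle inhibitor Cdkn1c 2225 and 526, the collagen gene Col9a3 6043 and 2117, and Car14, a carbonic anhydrase, 4659 and 1889.

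In APPSw 2 the haemoglobin gene Hba-a1 had a signal of 19525, against 11324 in APPSw 1 and 8678 and 10811 in controls. Hbb-b2 had 3323, against 1608 in APPSw 1 and 1327 and 2364 in controls. All 4 arrays are labelled male. Xist, the X-inactivation RNA, was between 134 and 277 on every array, and the Y-linked genes Eif2s3y and Uty were between 1070 and 1455 and between 682 and 835. The Y-linked gene Kdm5d was between 55.4 and 149.5.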
